A study of Mus musculus with 36 samples.

How the data were processed

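Whole bladder RNA of C57BL/6 mice was profiled by total RNA sequencing after bilateral adrenalectomy, the surgical removal of both adrenal glands and with them the main source of corticosterone. Per the labels, animals then received corticosterone (CORT, the main glucocorticoid of mice) timed to the inactive phase, or vehicle, and 36 libraries were made at 6 time labels from 4 to 24 h, with 3 replicates in each of the 12 groups. The replicate 3 libraries carry no time tag, so their time comes from their titles, and they were registered later than the others; they may be a separate batch, in which each of the 12 groups has 1 library. The labels do not say what time zero is, so times are given on the label clock. Nothing in the labels says that the 3 replicates of a group are separate animals, so p-values measure the spread between these samples, which may be partly technical. Libraries were rRNA-depleted and made with a directional kit, per the labels' protocols. The same protocol text describes RNA isolation from blood with globin removal, whereas the source of every sample is given as bladder. Differences of blood cell transcripts between treatments and times are therefore reported among the gene lists, but they do not show which tissue was used.

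The genome build is mm10, per the submitters' processing notes; the aligner and the counting program are not given in the sources used here. The authors deposited gene tables per treatment, each holding the 12 libraries of 2 replicate numbers, with 49585 features. The deposited values are a linear signal per gene that is never negative: in each table every library holds the same sorted set of values and every value is a multiple of 1/12, so these are read counts per gene that the authors quantile normalized over the 12 libraries of that table. Features with equal counts in a library were ranked in row order and so received slightly different values, which mainly affects low features. A further table per treatment held the same values as the table of replicates 1 and 2, with 13 feature names replaced by numbers. Another 4 deposited tables hold genes that the authors selected, as log2 values of the normalized signal plus 1, with limits of 2-fold and p 0.05 in their names; these genes were chosen on the same libraries and are not independent evidence. All 156 value columns used were matched to a sample by name. In the selected-gene tables of 18 libraries, 8 replicate 2 columns, 4 per treatment, hold the values of another library than the same name holds in the full tables. Those names also move libraries between treatments: vehicle 16 and 20 h replicate 2 stand as CORT 4 and 8 h. CORT 16 and 20 h replicate 2 stand as vehicle 4 and 8 h, and the rest change time only. The naming of the full tables was used throughout, and the other naming was run as an alternative.

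Because each table was normalized separately, a common scale was rebuilt. The mean of the 3 sets of sorted values of a treatment is the set that normalizing its 18 libraries together would give, and the mean over both treatments is that for all 36. Each library's features were ranked from its values in 2 tables and given the common values. On simulated counts this rebuild differed from direct normalization by at most 2.91e-11, and 100% of counts of 20 or less were recovered. Moving to the common scale changed the deviations of CORT libraries from their means by 0.00926 on the log2 scale (root mean square; largest change 0.100), against an SD of these deviations of 0.43; for vehicle the change was 0.00952 (largest 0.101) against 0.45. Sorted values also gave the mean total count per replicate number. The total of a single library cannot be taken from the normalized values, but its low counts can be numbered: a normalized value of 100 stood for 68 to 152 reads in single libraries (median 96), and 31555 to 32934 features had no read. With about 100 reads behind a value of 100, genes at normalized values of a few units rest on a few reads.

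Values were analysed as log2(value + 1), so that log2 fold changes understate those of low genes. Features at the lowest value in more than 50% of the libraries of a fit were left out. All tests across genes used limma, a linear model with moderated variances, with Benjamini-Hochberg adjustment at 0.05. Counts at an unadjusted p under 0.05 are given for scale only. Without any effect, a share of about 0.05 of the features tested would fall under that limit. Such counts are therefore no evidence of an effect by themselves, and several lie below that share. The time effect was a moderated F test over the 6 time labels within the table of replicates 1 and 2 of each treatment (12 libraries, 2 per time), as fixed for tables in which a library's values differ. The 24 h rhythm was a moderated F test of a cosine and a sine term over 18 libraries per treatment, giving the amplitude (log2, mean to peak) and the peak time. The interaction test asked over all 36 libraries whether these terms differ between treatments. The level comparison was the mean over the 6 times, CORT minus vehicle, from a fit of the 12 group means, which also gave the contrast at each time. These last contrasts were planned only for tables normalized together; they were run on the rebuilt common scale, a choice made after the files were seen, and the design had allowed for log2 or count tables where the files hold normalized linear values.

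Gene lists for the clock, glucocorticoid response, bladder cell types, immune cells, stress and metabolism (32 lists) were fixed together with the tests, the samples of each fit and most alternatives before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, for lists with at least 3 measured members, on the level contrast and on the half-cycle contrast, the mean of 16, 20 and 24 h minus that of 4, 8 and 12 h. Named genes follow a rule fixed in advance: the clock genes, the 10 genes with the largest change in each direction among those past the threshold (leaving out predicted genes; for rhythms by amplitude, split by a peak at 2 to 14 h or 14 to 26 h), the 10 with the smallest p where none passed, the members of each list with the smallest p, and 6 genes of bladder sensing and glucocorticoid signalling. Other names are said to have been chosen after their values were seen. Counts adjusted over a list alone are corrected within that list, not over the 32 lists or over the comparisons. Members of a list can be correlated, so such counts are not counts of separate findings.

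A clock time was fitted to each library from the 19 clock genes: the phase, in steps of 0.1 h, at which the vehicle rhythm correlated best with the library's deviations. The vehicle libraries of the same time label were left out of that template, and CORT deviations were taken from the mean of the CORT libraries at other times. Scatter and swing were compared by permuting the treatment labels within each time (1e+05 resamples).

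Alternatives were other low-value filters, a pseudocount of 0.1, median centring, an intensity trend, library weights, F tests without variance moderation, a 12 h harmonic, a time-factor interaction, a replicate block, and leaving out each replicate number and each library. No pair of libraries was identical: the smallest root mean square difference between 2 libraries was 0.294 on the log2 scale (median 0.466). The fits were tested on simulated data with 200 changed genes, all with a mean normalized value of at least 10, so recovery of lower genes was not measured. No rhythm was simulated in CORT, so recovery by the CORT rhythm fit was not measured either. Each simulated gene had the same spread in both treatments, whereas the clock genes varied more between CORT replicates (median ratio of SD 1.51). Among 50 genes with a simulated size of 0.5 and 50 of 1 on the log2 scale, the vehicle rhythm fit recovered 32 and 49, the interaction 25 and 46, the level contrast 41 and 49, the contrast at 4 h 11 and 35, and the vehicle time effect, with 12 libraries, 0 and 35. Camera and fry each called 10 of 10 changed lists and 0 of 40 unchanged ones. The simulated genes varied independently of each other, so these lists cannot show how often lists of correlated genes are called falsely. Gene symbols matched the GENCODE M21 annotation of mm10 for 47121 features (95.0%), from which coordinates were taken. The kit is directional, but whether counting used strand is not given, so overlapping and antisense genes are uncertain, as are multigene families such as globins and metallothioneins. Software was R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Values of some single genes are not reported here, though the fits and the counts per list include them.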

Results

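Total RNA of whole mouse bladder was sequenced after bilateral adrenalectomy in animals given corticosterone (CORT) or vehicle, in 36 libraries: 18 per treatment, 3 at each of the time labels 4, 8, 12, 16, 20 and 24 h. The series title names its subject as the control of the bladder's own clock and of the daily micturition pattern by glucocorticoids. The mean total count per library was 11016413 in CORT and 10682675 in vehicle, and between 9591304 and 12311336 by treatment and replicate number. Libraries of a group correlated with each other at a mean of 0.983 over genes and at 0.982 with libraries of other groups. The lowest mean correlation of a library with its own group was 0.979 (vehicle 16 h replicate 1). The first principal component held 12.2% of the variance; treatment accounted for a share of 0.164 of it, replicate number for 0.236 and time for 0.122.

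The first question was which transcripts of the vehicle bladder cycle over the day. Clock genes showed the clearest rhythms. Dbp, a transcription factor driven directly by the core clock, had normalized values of 1501 ± 509 at 12 h and 150.3 ± 14 at 20 h (SD, n = 3 each). It had a fitted amplitude of 1.71 ± 0.10 (log2, SE, n = 18 libraries), a 10.7-fold range from trough to peak and a peak at 10.3 h (limma, adjusted p = 2.18e-07). Nr1d1 (REV-ERB alpha), which represses Arntl, peaked at 7.88 h with an amplitude of 1.65 ± 0.10, and Ciart, another repressor, at 11.9 h with 2.14 ± 0.23. Per2, a repressor of the CLOCK and BMAL1 pair, peaked at 14.4 h (1.01 ± 0.07), Cry1 at 18.6 h (0.70 ± 0.06), and Arntl, which encodes BMAL1, at 23.7 h (1.20 ± 0.12). On mm10, Dbp lies on chromosome 7 at 45705088 to 45710203, Nr1d1 on chromosome 11 at 98767932 to 98775333, Per2 on chromosome 1 at 91415982 to 91459324 and Arntl on chromosome 7 at 113207465 to 113314126.

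By list, 9 of 10 clock repressors and 2 of 5 measured clock activators (Arntl among them) passed in vehicle. So did 3 of 4 genes listed as PAR bZIP outputs (Dbp, Tef and Nfil3). Adjusted over each list alone, 10, 4 and 4 passed. Nfil3 is counted in the PAR bZIP list here and below, although it encodes a bZIP repressor outside the PAR family. Between the repressors' peaks lay Nr1d2 at 10.1 h, Bhlhe41 at 10.8 h, Per3 at 11.9 h, Per1 at 13.7 h and Cry2 at 15.2 h, with Tef at 11.8 h and Nfil3 at 21.7 h. Clock, Npas2, Rora, Bhlhe40 and Hlf were not called, with adjusted p of 0.0697, 0.0836, 0.990, 0.267 and 0.197.

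In all, 78 of 17717 features had a 24 h rhythm in vehicle, 47 with a peak at over 2 to 14 h and 31 later. Outside the clock lists, the largest amplitudes in the first set were those of Tcap, which encodes a sarcomere protein (1.42 ± 0.25, peak 11.8 h), Car4, a carbonic anhydrase (1.14 ± 0.19, 3.72 h), and Chodl (1.13 ± 0.14, 7.5 h). They were followed by the myosin Myh7 (1.08 ± 0.15, 12.8 h), Cadps (1.02, 5.44 h), Diras2 (0.95, 5.69 h) and the mitotic cyclin Ccnb1 (0.87 ± 0.13, 7.03 h). In the second set they were those of Angptl7 (1.61 ± 0.20, 21.2 h), the xenobiotic-metabolizing Cyp1a1 (1.52 ± 0.24, 14.9 h), the carboxylesterase Ces1g (1.3 ± 0.18, 19.9 h), BC016579 (0.80, 15.8 h), Wnt6 (0.75, 18.7 h), Padi2 (0.72, 16.8 h) and Wnt16 (0.71, 14.3 h). Among 22 glucocorticoid-responsive genes, 4 passed (6 adjusted over the list alone): Per1, the metallothioneins Mt2 (0.71 ± 0.10, peak 8.77 h) and Mt1 (0.54 ± 0.09, 8.98 h), and Tsc22d3 (0.46 ± 0.07, 15.5 h). Ccnb1 was the only 1 of 10 cell division genes to pass over all genes (6 adjusted over the list alone, with a peak at 2 to 14 h in all 6). No cholesterol synthesis gene passed over all genes (0 of 13 by limma), but 11 did adjusted over the list alone, among them Idi1 (0.43 ± 0.09, 16.2 h). Of 6 genes of bladder sensing and glucocorticoid signalling fixed for naming, none was called. Vehicle amplitudes were 0.03 ± 0.06 for the stretch channel Piezo1 (adjusted p = 0.970), 0.28 ± 0.10 for the channel Trpv4 (0.368), 0.09 ± 0.10 for the gap junction gene Gja1 (0.875). They were 0.08 ± 0.12 for the nucleotide transporter Slc17a9 (0.933), 0.09 ± 0.07 for the glucocorticoid receptor Nr3c1 (0.792) and 0.17 ± 0.12 for Fkbp5 (0.770). The count of 78 was 166 with an intensity trend, 156 with library weights, 150 with a minimum mean of 10 and 135 with the more abundant 0.5 of features. It fell to 20, 4 and 10 without replicates 1, 2 and 3, to 51 without vehicle 4 h replicate 3 and to 50 without vehicle 16 h replicate 2, and was 148 without vehicle 12 h replicate 1. It was 17 without the 4 vehicle replicate 2 libraries that carry another name in other tables, and 0 by limma with those other names (641 at an unadjusted p under 0.05; both settings were chosen after the data were seen).

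In CORT the same genes were less regular. Dbp stood at 626 ± 144 at 4 h and 806 ± 633 at 24 h (normalized values, SD, n = 3), with a fitted amplitude of 0.86 ± 0.22 and a peak at 3.06 h (limma, adjusted p = 0.542). Nr1d1 had an amplitude of 0.88 ± 0.20 at 2.25 h (0.402), Arntl 0.62 ± 0.19 at 15.7 h (0.745), Ciart 1.19 ± 0.37 at 1.84 h (0.745) and Per2 0.31 ± 0.15 at 3.20 h (0.925). No feature of 17921 passed the rhythm test in CORT: limma called 0, with 1056 at an unadjusted p under 0.05, and F tests without moderation called 2. Adjusted over the list alone, 6 of 10 clock repressors, 2 of 5 activators and 2 of 4 PAR bZIP outputs passed. So did 7 of 15 endoplasmic reticulum folding genes, among them Hyou1 (0.18 ± 0.05, peak 20.2 h) and Pdia6 (0.22 ± 0.06, 22 h), and 3 of 13 immediate early genes. The 4 of 22 glucocorticoid-responsive genes that passed were Angptl4 (0.93 ± 0.21, 7.87 h), Mt1 (0.48 ± 0.12, 6.37 h), Mt2 (0.66 ± 0.17, 6.69 h) and Errfi1 (0.87 ± 0.24, 3.11 h). The smallest p over all genes were those of Ralgps2 (0.25 ± 0.03, adjusted p = 0.0710), Sall1 (0.98 ± 0.14, 0.0710), Mtag2 (1.13, 0.0842), Wnt6 (0.84 ± 0.13, 0.0842), Nol4l (0.28, 0.202) and, each at 0.275, Cx3cr1 (0.75), Slc26a5 (0.70), Brdt (0.52), Map3k13 (0.34) and Syt1 (0.51). Piezo1 (0.03 ± 0.07), Trpv4 (0.19 ± 0.10), Gja1 (0.16 ± 0.10), Slc17a9 (0.45 ± 0.17), Nr3c1 (0.09 ± 0.07) and Fkbp5 (0.73 ± 0.26) were not called, with adjusted p of 0.995, 0.937, 0.970, 0.836, 0.981 and 0.834. The count was 4 without CORT 4 h replicate 1, and 1 without CORT 8 h replicate 3, CORT 12 h replicate 2, CORT 16 h replicate 1 or replicate 3 of every time.

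**Figure D1:**
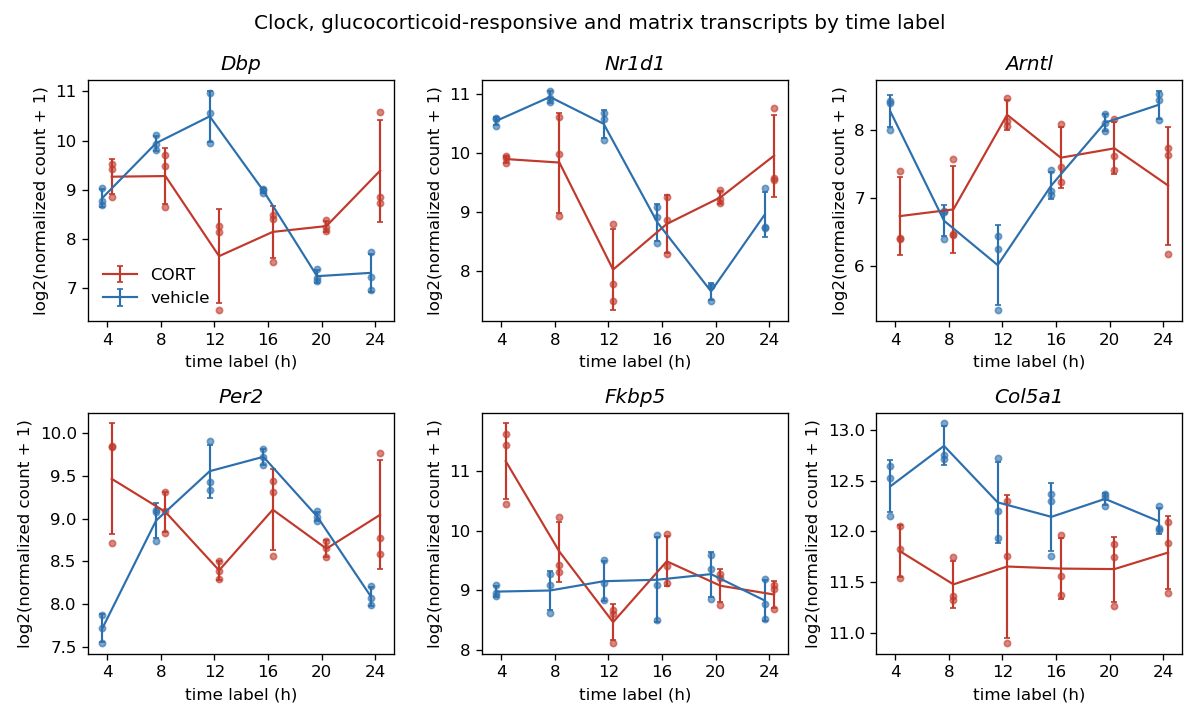
Normalized values (log2(value + 1)) of Dbp, Nr1d1, Arntl, Per2, Fkbp5 and Col5a1 against the time label in hours, for CORT and vehicle; points are single libraries and lines join means with their SD (n = 3). Vehicle Dbp runs from a mean of 10.49 at 12 h to 7.24 at 20 h, where CORT stands at 7.65 and 8.26, and Fkbp5 at 4 h is at 11.17 in CORT and 8.97 in vehicle.

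Whether the daily pattern differed between treatments was tested directly. The rhythm of 19 features of 17867 differed, and 11 of them were clock genes. Fitted peaks of CORT minus vehicle lay at -7.22 h for Dbp (95% interval -8.97 to -5.48; adjusted p = 5.92e-05 by limma over 36 libraries), -5.62 h for Nr1d1 (-7.22 to -4.03; 0.000245), -7.93 h for Arntl (-10.2 to -5.64; 0.000731) and -11.2 h for Per2 (-14.5 to -7.93; 0.000555). Differences for Tef, Per3, Ciart and Cry1 were -8.25, -7.80, -10.1 and -4.28 h; near 12 h a shift forward and one backward are equal. Amplitudes in CORT minus vehicle were -0.96 ± 0.45 for Ciart, -0.85 ± 0.24 for Dbp, -0.77 ± 0.22 for Nr1d1, -0.70 ± 0.17 for Per2, -0.60 ± 0.23 for Arntl, -0.51 ± 0.12 for Cry1, -0.39 ± 0.16 for Per3 and -0.35 ± 0.13 for Tef (log2, SE). By list, 8 of 10 repressors, 1 of 5 activators and 2 of 4 PAR bZIP outputs differed (10, 4 and 4 adjusted over the list alone). Over the 19 clock genes, the median absolute difference in peak time was 8.25 h. None of the 19 had a called rhythm in CORT over all genes (0 called, and 10 adjusted over the list alone). The CORT peak times, and the differences and intervals built on them, therefore rest on rhythms that were not called. For some genes the peak was hardly determined, as for Rora, with an interval of -32.0 to 55.3 h.

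Besides clock genes, the largest amplitude losses were those of the tetraspanin Tspan4 (-0.46, adjusted p = 0.0391) and the mitochondrial folate enzyme Mthfd1l (-0.30, 0.00223). Cx3cr1, the fractalkine receptor of macrophages and other immune cells on chromosome 9 (119901616 to 120069879), was the one feature with the larger amplitude in CORT, 0.73 against 0.27 (adjusted p = 0.0432). Its normalized value in CORT was 52.4 ± 25.2 at 4 h and 157 ± 28 at 20 h, against 161 ± 37 and 162 ± 28 in vehicle (SD, n = 3). Adjusted over the list alone, 1 of 22 glucocorticoid-responsive genes differed in rhythm (Per1). The interaction count was 11, 1 and 2 without replicates 1, 2 and 3. It was 10 without the 8 libraries named in 2 ways and 0 by limma with their other names. With those names 443 of 17867 features had an unadjusted p under 0.05, fewer than the share of 0.05 that chance alone would give.

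A clock time fitted to each library from 19 clock genes gave the same comparison library by library. In vehicle, 18 of 18 libraries lay within 2 h of their label, with a mean offset of 0.138 h. In CORT, 3 of 18 did, with a mean offset of 6.47 h, and 10 of 18 lay more than 6 h away. CORT libraries at 12 h read as 20.9, 22.1 and 23.6 h and those at 20 h as 2.7, 23.9 and 2.7 h, whereas the 3 at 24 h read as 11.5, 4.3 and 4.7 h. The resultant length of the offsets, which is 1 when all are equal, was 0.626 in CORT and 0.973 in vehicle (permutation p = 0.0135, one-sided). The fitted swing had a median of 0.57 in CORT and 0.92 in vehicle, on a scale where the vehicle template is 1 (permutation p = 0.00655, two-sided). The template comes from vehicle libraries at other times, which favours vehicle in both comparisons. CORT 8 h replicate 2 had a swing of 0.04 and a correlation with the template of 0.06, so its clock time was hardly determined. It still counts among the 10 libraries over 6 h away, in the mean offset and in the resultant length. The median correlation was 0.75 in CORT and 0.89 in vehicle. A low swing makes a fitted time less certain, so scatter and swing are not independent. The SD between replicates over the clock genes was 0.41 in CORT and 0.24 in vehicle (log2, median), a median ratio of 1.51, against 1.04 over all genes tested.

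**Figure D2:**
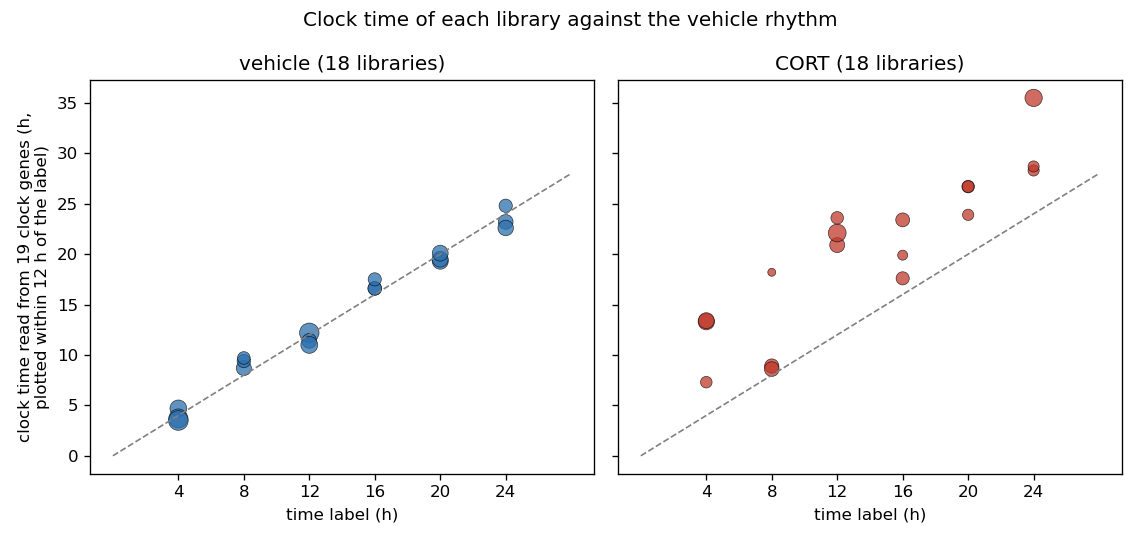
Clock time in hours fitted to each library from 19 clock genes, against its time label in hours, for CORT and vehicle; each point is 1 library, its size shows the fitted swing, and the dashed line marks equality with the label. All 18 vehicle libraries lie within 2 h of the line and 3 of 18 CORT libraries do.

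Later times (16, 20 and 24 h) were set against earlier times (4, 8 and 12 h) to ask which gene groups shift over the cycle. In vehicle, cholesterol synthesis genes were higher late in 13 of 13 members (median 0.26 on the log2 scale; camera adjusted p = 8.30e-09), as were T and NK cell markers in 8 of 9 (0.62; 0.00122). Neither list passed with an estimated correlation (adjusted p = 0.412 and 0.404 with an estimated correlation). Cell division genes (-0.48; 1.57e-05), interferon response genes (-0.33; 0.000975), clock repressors (-0.38; 0.00161) and collagens and matrix genes (-0.22; 0.00185) were lower late. These 4 did not pass either, with adjusted p = 0.404, 0.412, 0.412 and 0.604 with an estimated correlation. Smaller shifts were called by camera for endoplasmic reticulum folding (0.12), urothelium (0.12), endothelium (-0.14) and fatty acid oxidation genes (-0.10), with adjusted p = 0.412, 0.645, 0.604 and 0.412 with an estimated correlation, so that none of the 10 lists passed by it. Fry called 4: clock repressors (adjusted p = 0.0152), PAR bZIP outputs (0.00314), T and NK cell markers (0.0471) and cell division (0.0197).

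In CORT, glucocorticoid-responsive genes were lower late in all but 3 of 22 members (median -0.41; camera adjusted p = 2.62e-10), as were erythroid and globin genes (-0.37; 0.000124) and fatty acid oxidation genes (-0.11; 0.000248), while heat shock (0.23; 1.54e-06) and endoplasmic reticulum folding genes (0.18; 2.87e-08) were higher late. Each of these 5 calls was lost with adjusted p = 0.193 with an estimated correlation, and fry called 0 lists, with adjusted p of 0.119 for heat shock and 0.163 for glucocorticoid-responsive genes. The CORT count was 13 without replicate 1 and 11 without replicate 2. The shift itself differed between treatments for 9 lists by camera and for 0 by fry or with an estimated correlation. These included cholesterol synthesis (median difference -0.23; camera adjusted p = 4.31e-06), with adjusted p = 0.423 with an estimated correlation, and glucocorticoid-responsive genes (-0.32; 5.27e-06), with adjusted p = 0.352 with an estimated correlation.

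Any change over the 6 times, whatever its shape, was tested within the 12 libraries of replicates 1 and 2. In vehicle the smallest p were those of Myh7 and Nr1d1 (time means spanning 1.70 and 3.35 on the log2 scale; adjusted p = 0.0511 by limma for both), Angptl7 (3.64; 0.0904), Per2 (1.97; 0.183), Dbp (3.20; 0.183), Slc20a1, Hist1h4n, Rnd1, Spaca1 and Kdm8. Limma called 0 of 17697 features in vehicle, with 1634 at an unadjusted p under 0.05, and F tests without moderation called 0, with 1759. Adjusted over the list alone, 10 of 10 clock repressors, 3 of 4 PAR bZIP outputs, 7 of 13 cholesterol synthesis genes, 6 of 10 cell division genes and 5 of 22 glucocorticoid-responsive genes passed. In CORT, 1 of 18002 features passed, the predicted gene Gm6135 (adjusted p = 0.0474, 813 features at an unadjusted p under 0.05), which lies near the floor with a mean of 0.61 on the log2 scale and was chosen for naming after its values were seen. The next CORT genes were Fpr1, Ptprn2, Mettl24 and Pcdhga12 (adjusted p = 0.190 each), Fbxo24, Trp53cor1, Chrm5, Olfr1318, mt-Nd3 and Vmn1r32. Adjusted over the list alone, 2 of 22 glucocorticoid-responsive and 2 of 8 erythroid and globin genes passed in CORT. The CORT count was 0 by limma without any single one of its 12 libraries (688 to 1249 at an unadjusted p under 0.05) and 7 with replicates 2 and 3 in place of 1 and 2. The vehicle count was 131 with replicates 2 and 3 and 71 with all 18 libraries on the rebuilt scale (chosen after the data were seen). It was 1 without vehicle 4 h, 20 h or 24 h replicate 1 and 2 without vehicle 20 h replicate 2.

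The level of each transcript averaged over the day was compared between treatments on the rebuilt scale. Collagens and extracellular matrix genes were lower in CORT for 18 of 21 members (20 adjusted over the list alone; median -0.49 on the log2 scale). Among them were Col5a1 at -0.69 ± 0.11 (SE, n = 18 per treatment; 0.620 of the vehicle level; adjusted p = 0.0010), Col6a2 (-0.58 ± 0.10), Sparc (-0.49 ± 0.09) and Fbn1 (-0.66 ± 0.13). Endothelial markers were lower for 8 of 10 (10 adjusted over the list alone; median -0.37), including Vwf (-0.59 ± 0.08), Pecam1 (-0.38 ± 0.07), Tie1 (-0.45 ± 0.08) and Tek (-0.33 ± 0.06). Cell division genes were lower for 8 of 10 (9 adjusted over the list alone; median -0.86), including Ccna2 (-0.95 ± 0.12), Mki67 (-1.06 ± 0.16; 0.479 of the vehicle level), Top2a (-0.84 ± 0.14) and Ccnb1 (-0.88 ± 0.16), while Pcna, which also serves DNA repair, stood at 0.01 ± 0.04. Col5a1 lies on chromosome 2 at 27886425 to 28039514 and Mki67 on chromosome 7 at 135689784 to 135716361. In total 734 of 17867 features passed by limma, 230 higher and 504 lower in CORT. With library weights 3145 passed, 1666 of them higher, so the balance of directions depends on that choice.

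The camera tests of these 3 lists gave adjusted p of 1.49e-24, 4.13e-15 and 3.26e-14, and all 3 held with an estimated correlation (0.0199 each) and by fry. The interferon response had 3 of 12 genes lower in CORT (3 adjusted over the list alone; Rsad2 -0.54 ± 0.11, Bst2 -0.37 ± 0.08, Rtp4 -0.49 ± 0.12) and a median of -0.25 (camera 2.20e-05, fry 0.0110), with adjusted p = 0.146 with an estimated correlation. Fibroblast markers had 1 of 9 lower (Pi16 -0.44 ± 0.09; 4 adjusted over the list alone; median -0.13; camera 0.00242, fry 0.0120), with adjusted p = 0.146 with an estimated correlation. Bladder sensing and contraction genes had 1 of 23 lower, the stretch channel Piezo1 (-0.26 ± 0.07, adjusted p = 0.0271; 2 adjusted over the list alone; median -0.09; camera 0.0484, fry 0.0321), with adjusted p = 0.146 with an estimated correlation. Piezo1 lies on chromosome 8 at 122481698 to 122551329. Urothelial markers had a median of 0.17 with 0 of 19 called by limma (1 adjusted over the list alone, Upk3a, 0.25 ± 0.07; camera 0.000435, fry 0.186), with adjusted p = 0.661 with an estimated correlation. Camera also called glucocorticoid-responsive (0.17), fatty acid oxidation (0.12), macrophage (-0.10) and endoplasmic reticulum folding genes (-0.07). Their values were adjusted p = 0.722 with an estimated correlation for the first and 0.615 for the other 3, and fry called none of these 4 (0.199, 0.10, 0.186 and 0.189). Trpv4 (0.18 ± 0.10), Gja1 (-0.06 ± 0.09), Slc17a9 (-0.12 ± 0.14), Nr3c1 (-0.11 ± 0.07) and Fkbp5 (0.40 ± 0.13) were not called, with adjusted p of 0.330, 0.75, 0.695, 0.415 and 0.0928.

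Of single genes, the largest falls were those of genes used in mitosis and DNA replication, Fam64a (-1.32 ± 0.27), Pbk (-1.17 ± 0.16), Dtl (-1.13 ± 0.14), Nuf2 (-1.09 ± 0.21), Cenpf (-1.07 ± 0.18), Mki67 (-1.06 ± 0.16) and Prc1 (-1.05 ± 0.15), and of Klra2, Ppp2r2c and Celf6, which lie near the floor. The largest rises were those of Ly6k (1.09 ± 0.28), the chemokine Ccl28 (0.98 ± 0.24), Klhl31 (0.82 ± 0.24), Bex4 (0.74 ± 0.16), the ciliary gene Dnaaf3 (0.73 ± 0.20), Catsper3 (0.73 ± 0.21), Zmynd12 (0.66 ± 0.17), Dmrtc1a (0.60 ± 0.17), Cntnap3 (0.57 ± 0.10) and Fam183b (0.57 ± 0.14). Most of these 10 are low, with mean log2 values in CORT from 1.28 for Klhl31 to 5.30 for Cntnap3. Within each replicate number, which gives 6 libraries per treatment, limma called 0 genes (1312, 1301 and 2625 at an unadjusted p under 0.05 in numbers 1, 2 and 3). The list medians by number were -0.46, -0.56 and -0.55 for matrix, -0.37, -0.40 and -0.45 for endothelium and -0.45, -1.11 and -1.02 for cell division. Adipocyte markers, a sign of attached fat, stood at -0.27, 0.04 and 1.08, and by time at -1.13 at 4 h, 1.64 at 12 h and 2.44 at 16 h, with 0 of 9 called by limma at each of these times (0 adjusted over the list alone). The count was 411, 1 and 29 without replicates 1, 2 and 3, 6 without the 8 libraries named in 2 ways and 0 by limma with their other names (1434 at an unadjusted p under 0.05). It was 479, 437, 489, 1192 and 479 without CORT 8 h replicate 1, 12 h replicate 3, 16 h replicate 2, 24 h replicate 1 and 24 h replicate 2, and 455, 1282, 408, 479, 1226 and 476 without vehicle 8 h replicate 3, 12 h replicate 2, 12 h replicate 3, 16 h replicate 2, 16 h replicate 3 and 20 h replicate 3.

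**Figure D3:**
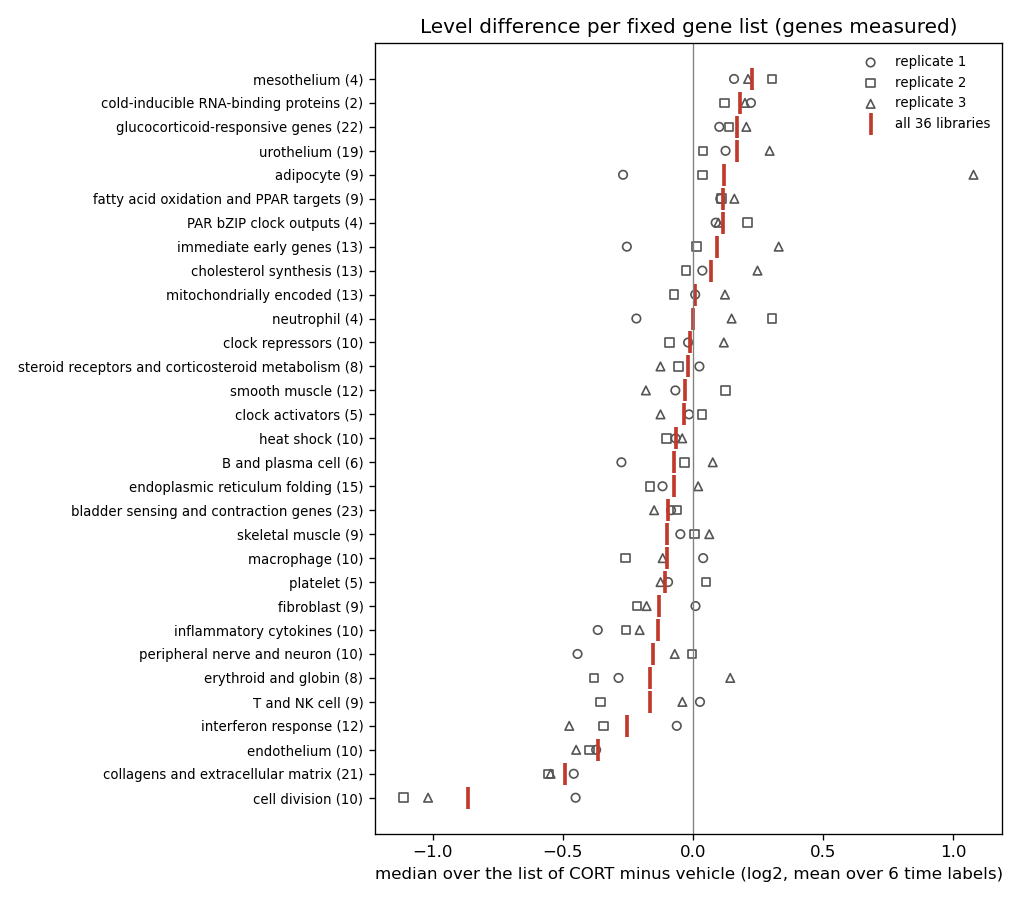
Median CORT minus vehicle difference (log2, horizontal axis) of each gene list over all 36 libraries and within each replicate number (12 libraries each). Matrix, endothelium and cell division lists lie below 0 for each number, with medians over all libraries of -0.49, -0.37 and -0.86; adipocyte markers range from -0.27 to 1.08.

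The treatments were also compared at each time, without a test between times. At 4 h, glucocorticoid-responsive genes were higher in CORT: 7 of 22 passed (17 adjusted over the list alone, all 17 higher), with a median of 1.03 on the log2 scale. Fkbp5, a receptor co-chaperone on chromosome 17 (28399094 to 28517527), stood at 2435 ± 923 in CORT and 502 ± 34 in vehicle (normalized values, SD, n = 3; log2 difference 2.19 ± 0.33, SE, adjusted p = 0.00160 by limma). Tsc22d3 (GILZ), on chromosome X (140539528 to 140600659), differed by 2.31 ± 0.28, the EGF receptor inhibitor Errfi1 by 2.27 ± 0.28, Per1 by 2.13 ± 0.28, Fam107a by 2.98 ± 0.54, the kinase Sgk1 by 1.49 ± 0.29 and Pdk4 by 1.14 ± 0.23. Per2 (1.75 ± 0.26) and Per1 were the 2 of 10 clock repressors to pass (6 adjusted over the list alone). In all 20 features were higher and 9 lower at 4 h. The 4 h count was 398 with library weights, 218 of them higher, 48 with a minimum mean of 10 and 45 with an intensity trend. It was 89 without replicate 1 and 0 by limma without replicate 2, replicate 3 or the libraries named in 2 ways (784, 567 and 726 at an unadjusted p under 0.05, against 1233 with all). Without CORT replicates 1, 2 and 3 alone it was 86, 6 and 8, and without vehicle replicates 1, 2 and 3 it was 14, 10 and 11.

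At 8 h most calls were falls, with 24 features higher and 118 lower in CORT. Matrix genes had 8 of 21 lower (19 adjusted over the list alone; median -1.10), including Col3a1 (-1.10 ± 0.20, adjusted p = 0.0111) and Col5a1 (-1.36 ± 0.27). Lower calls were also made for 4 of 10 cell division genes (8 adjusted over the list alone; Top2a -1.67 ± 0.35), 3 of 12 interferon response genes (10; Rtp4 -1.41 ± 0.30) and 2 of 10 endothelial markers (9; Vwf -1.13 ± 0.19). The progesterone receptor Pgr (-2.12 ± 0.49) and the macrophage marker Adgre1 (-0.59 ± 0.14) were each the 1 member of their list to pass. Medians were also low for inflammatory cytokines (-1.02), immediate early genes (-0.83) and neutrophil markers (-0.63) at 8 h, of which limma called 0 members over all genes (0, 0 and 1 adjusted over the list alone). At 24 h the medians of the first 2 lists were 1.02 and 1.08, again with 0 called by limma (1 and 0 adjusted over the list alone). The 8 h count was 975 with library weights, 295 of them higher, 267 with a minimum mean of 10 (52 higher) and 224 with an intensity trend (38 higher). It was 70, 1 and 4 without replicates 1, 2 and 3 and 0 by limma without the libraries named in 2 ways (1650 at an unadjusted p under 0.05, against 2706 with all). The count was 11, 24 and 287 without CORT replicate 1, 2 and 3 alone and 14 and 5 without vehicle replicates 2 and 3.

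At 12 h, 1 feature was higher in CORT and 7 were lower, all but Lingo1 (-2.60 ± 0.42) being clock genes: Arntl (2.21 ± 0.36), Ciart (-4.40 ± 0.71), Dbp (-2.85 ± 0.41), Nr1d1 (-2.47 ± 0.34), Bhlhe41 (-1.40 ± 0.25), Nr1d2 (-1.19 ± 0.20) and Tef (-1.19 ± 0.23). At 16 h, 2 replication genes were lower, Dtl (-2.31 ± 0.35) and Pole (-1.54 ± 0.25). At 20 h limma called 0 (1073 at an unadjusted p under 0.05), and adjusted over the list alone 4 of 10 clock repressors passed. At 24 h, 6 were lower: H2-Ab1 (-0.79 ± 0.12), Cd74 (-0.81 ± 0.13) and H2-Eb1 (-0.81 ± 0.13), which serve MHC class II antigen presentation, and Themis2, Col6a4 and Chp2. Lingo1, Pole and the 24 h genes were named after their values were seen. Adjusted over the list alone, 7 of 10 clock repressors were higher and 7 of 10 macrophage markers lower in CORT at 24 h. With library weights the counts were 13 at 12 h, 31 at 16 h, 21 at 20 h and 206 at 24 h (82 higher); at 24 h they were 17 with a minimum mean of 10, 11 with the more abundant 0.5 of features and 10 with an intensity trend. Without replicate 2 or 3 limma called 0 at 12 h (913 and 598 at an unadjusted p under 0.05), and the count was 3, 1 and 4 without CORT replicate 2, vehicle replicate 1 and vehicle replicate 3. The 16 h count was 0 without replicate 1 or 2 of both treatments (658 and 710 at an unadjusted p under 0.05) or replicate 2 of CORT or vehicle alone (606 and 968), and 1 without vehicle replicate 3. The 20 h count was 68 without replicate 1 and 55 without vehicle replicate 1. The 24 h count was 0 without replicate 1, 2 or 3 of both treatments (1267, 742 and 943 at an unadjusted p under 0.05) and without CORT replicate 3, vehicle replicate 1 or vehicle replicate 3 (1059, 922 and 977).

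The authors' selected genes were compared with the time effect. In their lists from 12 libraries, 455 CORT and 718 vehicle genes matched by name, of which 1 and 0 passed the limma time test at an adjusted 0.05, and 218 and 401 met the limits of the list names (2-fold and unadjusted p 0.05). Features at the lowest value in more than 50% of the 12 libraries were left out of both tests, so listed genes of that kind could not be counted. In the lists from 18 libraries, 25.1% of the CORT and 25.2% of the vehicle genes met those limits over 18 libraries with the full-table names, and 50.2% and 49.1% with the names of the selected-gene tables. These shares were taken without the low-value filter, so they cannot be set against the counts from 12 libraries. By the full-table names 7 of the 19 clock genes met the limits in CORT and 16 in vehicle, by the other names 2 and 10. Many listed genes were low: 59.1% and 63.3% of the CORT lists from 12 and 18 libraries and 34% and 64.6% of the vehicle lists had 5 reads or fewer in every library. The lists were chosen on these same libraries and are not independent of the tests.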

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

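Tests chosen only after the result was seen are those of read depth, of the fibroblast share, of the last draw of splits, of the make-up of the largest split, of pairs of the same time and number, of a wrong label at CORT 24 h, of the names of 8 libraries, and of the settings that use other names for those libraries. The level and single-time comparisons weighed here were themselves chosen after the data were seen.

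The rhythm of 19 transcripts differed between CORT and vehicle by a test of the difference itself. The adjusted p from limma over 36 libraries were 5.92e-05 for Dbp, 0.000245 for Nr1d1, 0.000555 for Per2, Tef and Chp2, 0.000590 for Nr1d2 and Ciart, 0.000731 for Arntl, 0.000993 for Bhlhe41, 0.00223 for Mthfd1l, 0.00272 for Per3, 0.00984 for Rasl11a, 0.0130 for Wee1, 0.0300 for Cry2, 0.0391 for Fndc5, Cry1, Insm2 and Tspan4, and 0.0432 for Cx3cr1. Of those outside the clock lists, Chp2 peaked at 15.7 h in CORT and 2.60 h in vehicle, Rasl11a at 11.9 and 23.7 h, the mitotic inhibitor kinase Wee1 at 3.88 and 15.3 h, Fndc5 at 3.50 and 9.57 h and Insm2 at 7.65 and 19.3 h. Treatment labels were permuted within each time: 2 of 100 splits, the real one included, gave at least 19 calls, a share under 0.05. One other split called 2026 genes, many times the real count, with 18 of 36 libraries in their own treatment. As such a split can give more calls than the real one, the share alone does not exclude chance. So many calls point to some structure of the samples, which was not identified. At 6 of 6 times it put both libraries of one replicate number in one arm and both of another number in the other arm, which a share of 0.6 of all splits does at a given time. A link to the numbers is neither shown nor excluded: over the 18 pairs of the same time and number, deviations from the group means had a mean correlation of 0.0703. These splits were drawn 3 times: the first draw of 100 was replaced by this one when the scripts were divided, and the last was added later. The first and last each held 1 split as large, the real one, with 2 and 9 calls in the highest other split, so the highest other count depends strongly on the draw.

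The first pattern weighed is the smaller and displaced clock rhythm in CORT. Fewer reads as the cause are argued against by the mean total count of CORT libraries, 1.03 times that of vehicle, and a single wrong label at CORT 24 h by the 16 interaction calls made without its replicate 1, whose clock time lay 11.5 h from its label. Both a scatter of clock times between CORT libraries (resultant length lower by 0.348 than in vehicle, permutation p = 0.0135, one-sided) and a smaller median swing (0.614 of vehicle, permutation p = 0.00655, two-sided; single libraries span 0.04 to 1.34 in CORT and 0.54 to 1.70 in vehicle) showed the values they need, although the template comes from vehicle. A low swing makes a fitted clock time less certain, so these 2 tests are not independent. The hypothesis left open is that CORT may shift the bladder clock, by an amount that varies, and damp it. The resultant length pools all 18 CORT offsets. It therefore cannot tell a shift that varies between libraries from one that varies with the time label. Offsets were 8.9, 10.1 and 11.6 h at 12 h and 6.7, 3.9 and 6.7 h at 20 h. At 8 h they were 0.9, 10.2 and 0.6 h, the 10.2 h being that of the library with a swing of 0.04. The mean offset of 6.47 h was read against a vehicle template whose 19 genes include Per1, also a member of the glucocorticoid-responsive list. A response of single template genes to CORT was not told apart from a clock shift by a test. Of label errors across several CORT libraries, only the other names of 4 replicate 2 libraries were tested, of which 3 of 4 lay nearer their full-table group over the clock genes and 4 of 4 over all genes.

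The second pattern is that 8 replicate 2 libraries have 2 sets of names. By the full-table names, 7 of the 8 libraries lay nearer to replicates 1 and 3 of their group over the clock genes (8 of 8 over all genes), and 1 of the 8 lay nearer to the group that the 18-library tables of selected genes name. This argues against shifted names in the full tables and is consistent with shifted names in the selected-gene tables; the exception is CORT 8 h replicate 2, whose fitted swing was 0.04. With the selected-table names, which place some of these libraries in the other treatment, limma called 0 rhythms in vehicle and 0 interactions (641 and 443 at an unadjusted p under 0.05). Authors' genes chosen from 18 libraries met their own limits more often with those names, 50.2% against 25.1% in CORT and 49.1% against 25.2% in vehicle, so the selection may have used them.

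The third pattern is the lower level of endothelial, matrix and cell division transcripts in CORT. A difference of the replicate 2 libraries alone is argued against by a correlation over genes of 0.239 between the differences in replicates 1 and 3. That correlation is low and covers all 17867 genes tested, not these lists. In replicates 1 and 3 the medians were -0.46 and -0.55 for matrix, -0.37 and -0.45 for endothelium and -0.45 and -1.02 for cell division. Exchanged names are argued against by the cell division median, which without the 8 libraries was 0.846 of that with them. Calls of single genes did depend on these libraries. The 734 level calls became 1 without replicate 2 and 6 without the 8, against 411 and 29 without replicates 1 and 3. Fewer reads in CORT are argued against by the depth ratio of 1.03. A smaller share of fibroblasts as the whole source of the matrix fall is argued against by the fibroblast median of -0.13, which lay 0.362 above the matrix median, with an SD over the 9 markers of 0.163, and the smooth muscle median was -0.03. An effect of CORT on proliferation and matrix synthesis, or fewer vessels or dividing cells in the tissue, may each account for what is left, and these were not told apart by a test.

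Lists whose shift from earlier to later times differed between treatments by camera were cholesterol synthesis (adjusted p = 4.31e-06), glucocorticoid-responsive genes (5.27e-06), collagens and matrix (5.08e-05), interferon response (0.00117), T and NK cell markers (0.00351), cell division (0.00351), clock repressors (0.00423), urothelium (0.00423) and mitochondrially encoded genes (0.0222). With an estimated correlation camera called 0 of the 9 and fry called 0. The adjusted p with an estimated correlation were 0.352 for glucocorticoid-responsive genes and T and NK cell markers, 0.382 for interferon response, 0.423 for cholesterol synthesis, matrix, cell division and clock repressors, 0.482 for mitochondrially encoded genes and 0.579 for urothelium.

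Other splits of the same samples were counted for each comparison. Permuted time labels gave as many calls as the real 78 vehicle rhythms in 1 of 100 splits, the real one (highest other 2), so chance is excluded there. For a real count of 0 every split has as many, so the counts of splits decide nothing there: 100 of 100 for the CORT rhythm (highest other 2; limma, 1056 at an unadjusted p under 0.05, F tests without moderation 2) and 100 of 100 for the vehicle time effect (highest other 8; limma, 1634 at an unadjusted p under 0.05, F tests without moderation 0). As many as the 1 time effect in CORT came in 51 of 100 (highest other 6), so chance is not excluded for it. Permuted treatment labels gave as many as the 734 level calls in 1 of 100 splits (highest other 2), so chance is excluded; the first and last draws also held 1 of 100 as large, with 55 and 4 calls in the highest other split. For single times 10 splits are too few for a share under 0.05. The real and highest other counts were 29 and 0 at 4 h (1 of 10 splits as large), 142 and 26 at 8 h (1 of 10), and 8 and 87 at 12 h (3 of 10). They were 2 and 0 at 16 h (1 of 10), 0 and 0 at 20 h (10 of 10; limma, 1073 at an unadjusted p under 0.05) and 6 and 1 at 24 h (1 of 10).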

How the results depend on the processing

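Tests chosen only after the data were seen are all those of levels and single times, the minimum mean of 10, the fits of 18 libraries for the time effect the 2 settings on library names and the pairs of the same time and number; the other tests of this part were planned.

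Over all settings, 202 counts kept within 1.5 times the reported one and 165 did not; of values of single genes 4327 kept direction and side of the threshold, 514 lost a call, 99 gained one and 21 turned. Depth limits the low genes, on which the filters and the pseudocount act; their effects are given below. The cause was not tested for any move below unless the setting itself removes features or libraries.

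Without a low-value filter the counts were 50 (CORT time effect), 55 (vehicle time effect) and 1 (20 h). With the more abundant 0.5 of features they were 0 (239 at an unadjusted p under 0.05, limma), 4, 1 (CORT rhythm), 135 (vehicle rhythm), 0 at 16 h (247 unadjusted) and 11 at 24 h; these 2 settings change how many features are tested. With a mean normalized value of at least 10 they were 0 (CORT time effect, 524 unadjusted), 3 (vehicle time effect), 1 (CORT rhythm), 150 (vehicle rhythm), 48 (4 h), 267 (8 h) and 17 (24 h). A pseudocount of 0.1 gave 28, 6 and 1 for the time effects in CORT and vehicle and the CORT rhythm. An intensity trend (limma-trend) gave 0 (CORT time effect, 710 unadjusted), 7 (vehicle time effect), 1 (CORT rhythm), 166 (vehicle rhythm), 45 (4 h), 224 (8 h) and 10 (24 h). Library weights (arrayWeights) gave 0 (CORT time effect, 895 unadjusted), 2 (vehicle time effect), 2 (CORT rhythm), 156 (vehicle rhythm), 3145 (level, 1666 higher in CORT), 398 (4 h), 975 (8 h, 295 higher), 13 (12 h), 31 (16 h), 21 (20 h) and 206 (24 h). F tests without moderation gave 2 CORT rhythms. The limits of the selected-gene tables gave 338 and 530 time effects and 218, 13, 401 and 18 of the authors' CORT and vehicle genes from 12 and 18 libraries (CORT first). These came from the fits of the 12 libraries of replicates 1 and 2 with the low-value filter. The shares given in the Results for the lists from 18 libraries used 18 libraries without that filter, so the values differ. All 18 libraries gave 3 and 71 time effects, with 46 and 5 of the vehicle lists.

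With the selected-table names limma called 0 vehicle rhythms, 0 interactions, 0 levels, 2 at 4 h and 0 at 8, 12, 16 and 24 h (641, 443, 1434, 532, 558, 451 and 832 at an unadjusted p under 0.05 for the 7 counts of 0). Without those libraries it called 17 vehicle rhythms, 10 interactions, 6 levels, 1 at 20 h and 0 at 4, 8 and 16 h (726, 1650 and 792 unadjusted), from fewer samples. Camera with an estimated correlation called 0, 0 and 0 lists for the half-cycle in CORT, vehicle and their difference and 3 for level; fry called 0, 4, 0 and 6.

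Leaving out a replicate or library gave ranges of 0 to 7 (CORT time effect), 0 to 131 (vehicle time effect), 0 to 4 (CORT rhythm), 4 to 148 (vehicle rhythm) and 1 to 23 (interaction). The ranges were 1 to 1282 (level), 0 to 89 (4 h), 1 to 287 (8 h), 0 to 10 (12 h), 0 to 3 (16 h), 0 to 68 (20 h) and 0 to 9 (24 h), where the counts of 0 are from limma, beside 567 to 2395 at an unadjusted p under 0.05. Lists ranged from 5 to 13 (CORT half-cycle), 8 to 13 (vehicle), 6 to 11 (difference) and 6 to 13 (level), and the median clock peak difference from 7.76 to 8.56 h.

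The labels do not say that a replicate number marks shared animals or a shared batch, and 5 of 18 pairs of the same time and number correlated over 0.1, so the numbers were not used as pairs; a link to them is not excluded. Same-numbered libraries deviated together with a mean correlation of 0.0859, 0.0369 and 0.0450 for numbers 1, 2 and 3, against -0.0279 for different numbers, and 25 of 36 libraries correlated best with their own number, a hint from the data, not the design. Deviations sum to 0 over the 3 libraries of a group, so the value for different numbers follows from those for same numbers and is no separate baseline. With the replicate number as a block the counts were 0 (CORT time effect, 924 unadjusted, limma), 1 (CORT rhythm), 1240 (level, 537 higher in CORT), 52 (4 h), 262 (8 h, 65 higher) and 10 (24 h); 98 vehicle rhythms and 17 interactions stayed within 1.5 times.

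Values that turned (a peak moved by over 6 h, or a difference of amplitudes that changed sign) belong to genes not called in those fits. With the selected-table names the amplitude was 0.068 for Rora in CORT and 0.10 for Piezo1 in vehicle, and the amplitude difference of Bhlhe40 was 0.013. Without the double-named libraries Rora had 0.058 in CORT and 0.021 in vehicle. The others turned when a replicate or library was left out. Their ranges over those fits were 0.099 to 0.89 (Chrm5), 0.20 to 0.83 (Olfr1318), 0.13 to 0.86 (Ptprn2) and 0.057 to 0.46 (mt-Nd3) for the CORT time effect. For the CORT rhythm they were 0.020 to 0.11 (Rora), 0.019 to 0.057 (Piezo1) and 0.016 to 0.25 (Hlf), and for the vehicle rhythm 0.0099 to 0.072 (Piezo1) and 0.0024 to 0.096 (Rora). The amplitude difference of Rora ranged from -0.0070 to 0.096.

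Quantile normalization as an alternative was not run, because all libraries already share one set of values; median centring left 78 vehicle rhythms and 19 interactions.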

Other observations

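The genes and lists below were chosen after their values were seen, and no tests were added for them; values are CORT minus vehicle on the log2 scale with the SE and adjusted p from limma. At 4 h, genes outside the glucocorticoid-responsive list passed as well. Cx3cr1 (-1.67 ± 0.28, 0.00631) and the apelin receptor Aplnr (-1.67 ± 0.35, 0.0445) were lower in CORT. Amica1 (2.08 ± 0.35, 0.00526), Ms4a6b (1.51 ± 0.28, 0.0187), Ms4a4a (1.93 ± 0.40, 0.0457), the NADPH oxidase subunit Ncf1 (1.21 ± 0.26, 0.0465) and the RNA sensor Tlr7 (0.99 ± 0.19, 0.0236) were higher. The 29 calls at 4 h became 86 without CORT replicate 1, 6 without CORT replicate 2, 8 without CORT replicate 3, and 14, 10 and 11 without vehicle replicates 1, 2 and 3.

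Averaged over the day, both cold-inducible RNA-binding proteins passed adjusted over the list alone (2 of 2; Cirbp 0.22 ± 0.08 and Rbm3 0.14 ± 0.07, with adjusted p over all genes of 0.103 and 0.233). The neuronal hydrolase Uchl1 (0.34 ± 0.08, 0.0198) was the 1 of 10 nerve genes called, and Actn3 of fast muscle fibres (0.38 ± 0.10, 0.0276) the 1 of 9 skeletal muscle genes. Markers that blood would carry were not called: the erythroid and globin list had a median of -0.16, with -0.29, -0.38 and 0.14 in replicate numbers 1, 2 and 3, and the platelet list one of -0.11.

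Further genes had a rhythm in vehicle. Krt4, a keratin of stratified epithelia, had an amplitude of 0.74 and a peak at 11.5 h (adjusted p = 0.0181), and Col17a1 of the epithelial anchoring complex 0.62 at 11.6 h (0.0187). The growth factor Nrg1 peaked at 13.8 h (0.84, 0.00585), the decoy receptor Il1r2 at 13 h (0.57, 0.00813), the thyroid hormone receptor Thra at 4.33 h (0.40, 0.00365), and Cdc25b, a phosphatase that promotes mitosis, at 6.33 h (0.36, 0.00813), close to Ccnb1 at 7.03 h.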
